A study of Homo sapiens with 10 samples.

How the data were processed

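Gene expression was measured by poly(A) RNA sequencing in the human glioblastoma lines DBTRG-05MG and U87 at 0, 6, 12, 24 and 48 h of dibutyryl cAMP. The labels give 1 mM and times up to 48 h, whereas the series description gives another unit of dose and a longer treatment; the labels were followed. The deposited table was read as FPKM (fragments normalised for transcript length and library size) for 20379 genes in 10 libraries. The labels do not state the unit, which was inferred from the values. The lowest values of a library step in whole reads scaled by transcript length, and 50.5% of 6946 low values lay within 0.05 read of a whole number. Such steps would also appear in other units scaled by transcript length, so FPKM remains an inference. The submitters' processing notes name HISAT, Bowtie2 and RSEM with the human build hg38, without versions. A value of 0.002 stands for 0 in the table and was read as 0. Spreadsheet software had turned 25 gene symbols into dates; 19 of these passed the filter and were tested, but none was named.

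Read counts were not used here. Relative depth was estimated from the size of the step of 1 read at low values, over 2293 genes, and ran from 100 to 116.8% of the first library. Its absolute scale, about 8.9 M fragments for that library (quartiles 7.8 and 8.9 over 220 genes with 1 annotated transcript), is approximate, so no counting interval is given for a gene. A value of 0 in this table means not detectable at this depth. Gene positions came from GENCODE release 29 on GRCh38, in which 18305 symbols were found, 16450 of them protein-coding.

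Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, for the 12352 genes with a mean of at least 1 FPKM over all libraries. Changes at each time used a fit with cell line as a block and time as a factor, which leaves 4 residual degrees of freedom, and each later time was compared with 0 h. The same cell line supplied each series of libraries, so the pairing by line comes from the design. As a check, 717 genes were at least 4-fold apart between the lines in the same direction at all 5 times. The 4 comparisons share the 0 h libraries and so share their chance values. Differences in time course were tested as the product of line and the rank of time, with 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The spread behind the tests of changes at each time is the disagreement between the lines, pooled over all 5 times. Its median SD was 0.27 on the log2 scale, and a response present in 1 line alone widens it. The spread behind the trend test is the scatter of the libraries around the straight trend of each line.

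Gene lists for cAMP signalling, inflammation, senescence, metabolism, cell division, stress, cell types and RNA quality, 34 in all, were fixed with the tests and the naming rule before the data were examined. Each was tested against the other genes with limma's camera, two-sided, with a preset correlation of 0.01 and, as an alternative, an estimated correlation, adjusted over the lists. Members were also adjusted over the list alone. The median of a list in each line was set beside 10000 random lists matched on expression. Several lists share members, among them IL6 and IL11. Within a line only trends over time were tested, a choice made after seeing the data. Counts of genes at least 2-fold from 0 h are sizes.

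The rule for named genes took, at 6 h and at 48 h, the 10 higher and 10 lower genes with the largest change in the line that changed less, those past the threshold first and then by size alone among genes with a mean of at least 5 FPKM. It added genes with differing trends, 5 more by the difference at 48 h in the direction that had none, up to 4 members of each list with the largest mean change, 10 genes per direction for the difference between the lines, and a fixed set of genes on IL-6, glycolysis, senescence and cAMP. Members outside the rule that make up a small count (PMEPA1, ID3, FAS and HSPH1) were chosen after their values were seen. Some genes that the rule names are not reported here.

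The fits were tested on simulated data with independent noise, in which a change at 48 h was equal in both lines. The shares recovered need not hold for the real data. With 50 genes at each size, the 48 h comparison recovered 16, 92, 100 and 100% of changes of 1, 2, 3 and 4 log2 units, with 8 of 12152 unchanged genes called, and the trend difference recovered 4, 46, 86 and 98%, with 10 called. Alternatives were the threshold, the pseudocount, the filter, scaling by median or upper quartile, no mean-variance trend, no replicate block, time as hours or log2 hours, a rank-based camera, and leaving out each library in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the rest.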

Results

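RNA was measured by poly(A) sequencing in DBTRG-05MG and U87, 2 established human glioblastoma lines, at 0, 6, 12, 24 and 48 h of 1 mM dibutyryl cAMP, a cell-permeable analogue of cyclic AMP that activates protein kinase A. The series holds 10 libraries, with 1 library for each line and time and so no replicates. The p-values for changes at each time therefore set the mean change of the 2 lines against their disagreement over all 5 times. A gene that moved alike in both lines at a given time can miss the threshold through disagreement at other times. The p-values for trends set the difference between the lines against the scatter around each line's own trend. There were no untreated libraries at the later times against which time in culture could be read. The deposited table, read as FPKM, covered 20379 genes, of which 12352 with a mean of at least 1 FPKM were tested. Relative depth ran from 100 to 116.8% of that of the DBTRG-05MG 0 h library. This corresponds to about 8.9 to 10.4 M fragments by an estimate from 220 genes. Total FPKM ran from 405322 to 487290. The non-coding RNA BCYRN1 alone took 3.37, 3.1, 0.58, 0.87 and 1.4% of it in the DBTRG-05MG libraries at 0, 6, 12, 24 and 48 h and 7.38 to 13.31% in the U87 libraries.

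The starting point of the 2 lines differed widely. DBTRG-05MG had the higher levels of the antiviral genes IFITM1 (787.8 FPKM as the mean of its 5 libraries), MX1 (528 FPKM), IFI27 (541 FPKM), OAS1 (239 FPKM) and BST2 (241 FPKM). It also had more of the keratin KRT18 (336 FPKM), the chemokine-like RARRES2 (290.01 FPKM), SERPINB5 (218 FPKM), the metalloprotease inhibitor TIMP3 (193 FPKM) and LOC100505817 (247 FPKM). U87 had more of the secreted factors CSF3 (639 FPKM), IL1B (498 FPKM), HGF (112 FPKM) and the BMP antagonist GREM1 (279 FPKM). It also had more of SMOC1 (244 FPKM), BASP1 (221 FPKM), IER3 (129 FPKM), MLPH (106 FPKM), BDKRB1 (77.3 FPKM) and PSG4 (53.7 FPKM). In all, 558 genes were at least 4-fold higher in DBTRG-05MG at each of the 5 times and 159 in U87. These are sizes, with no test behind them.

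The first comparison asked what differed after 6 h of dibutyryl cAMP. The interleukin genes IL11 and IL6, which encode cytokines that signal through gp130, stood out in both lines. IL11 rose from 8.82 to 269.9 FPKM in DBTRG-05MG and from 5.9 to 187 FPKM in U87. The mean log2 change of IL11 was 4.78 ± 0.43 (SE of the fit over all 5 times, n = 2 lines, limma adjusted p = 0.0173). IL6 was higher by a like factor in each line, from 2.95 to 19.9 FPKM and from 13.6 to 87.8 FPKM. Its mean log2 change of 2.51 ± 0.43 missed the threshold over all genes (limma adjusted p = 0.208). On GRCh38, IL11 lies on chromosome 19 (55364389 to 55370463) and IL6 on chromosome 7 (22725884 to 22732002).

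Known targets of cAMP and its transcription factor CREB were higher in both lines at 6 h. Of 33 tested members of the list, 12 rose when adjusted over the list alone and 21 were higher in both lines. DIO2, which activates thyroid hormone, rose from 2.74 to 19.5 FPKM in DBTRG-05MG and from 3.68 to 155 FPKM in U87. PDE4B, a phosphodiesterase that breaks down cAMP, rose from 2.05 to 11.6 FPKM and from 7.52 to 36.3 FPKM. The MAP kinase phosphatase DUSP1 rose from 12.6 to 133 FPKM and from 45.5 to 117 FPKM. The orphan nuclear receptor NR4A2 rose from 0.57 to 2.8 FPKM and from 0.64 to 9.48 FPKM. PDE4D and the CREB-family gene CREM were among the other members that rose. NR4A1 stood at 12.95 FPKM in DBTRG-05MG and 2.16 FPKM in U87 after 1.36 and 2.31 FPKM at 0 h. The coactivator gene PPARGC1A went from 0.73 to 5.33 FPKM in U87 and started at 16.7 FPKM in DBTRG-05MG. The list test (limma's camera) gave adjusted p = 3.44e-17, and adjusted p = 0.0519 with an estimated correlation. Among 26 components of the cAMP pathway itself, 0 passed adjusted over the list alone.

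Secreted factors and targets of TGF-beta came next at 6 h. IL6 and IL11 were the 2 of 35 secretory cytokines and growth factors that rose adjusted over the list alone. Camera gave these cytokines adjusted p = 2.3e-06, and adjusted p = 0.483 with an estimated correlation. Among 24 TGF-beta targets, PMEPA1 and ID3 rose adjusted over the list alone, by 2.35 ± 0.5 and 1.04 ± 0.24 on the log2 scale (SE), and 16 were higher in both lines. For the TGF-beta targets as a list, camera gave adjusted p = 1.63e-08, and adjusted p = 0.186 with an estimated correlation. For NF-kappaB targets, IL6 was the 1 of 31 that rose adjusted over the list alone. NF-kappaB targets as a list had adjusted p = 6.15e-05, and adjusted p = 0.515 with an estimated correlation. The list for IL6 signalling through JAK and STAT3 gave 2 of 28, again IL6 and IL11. As a list, IL6 signalling had adjusted p = 0.0103, and adjusted p = 0.26 with an estimated correlation. PMEPA1 and ID3, like FAS and HSPH1 at 48 h, were named after their values were seen.

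Other lists were called at 6 h with 0 members past the threshold adjusted over the list alone. Ribosomal proteins lay higher (adjusted p = 0.00212, and adjusted p = 0.861 with an estimated correlation). So did mesenchymal genes (adjusted p = 0.00442, and adjusted p = 0.515 with an estimated correlation) and secreted proteases and matrix genes (adjusted p = 0.0265, and adjusted p = 0.483 with an estimated correlation), the last of these with a median log2 change of 0.09 in DBTRG-05MG and -0.01 in U87. Replication-dependent histones, whose transcripts mostly lack poly(A) tails and so bear on RNA quality and selection, were higher too (adjusted p = 0.0302, and adjusted p = 0.763 with an estimated correlation). The G1/S and DNA replication list was called lower in the mean of both lines (adjusted p = 0.00793, and adjusted p = 0.861 with an estimated correlation), but 30 of its 49 members moved in opposite directions. Its median relative to all genes was 0.14 in DBTRG-05MG (35 members higher, 14 lower) and -0.53 in U87 (3 higher, 46 lower). In both lines 5 of 6 oligodendrocyte markers were lower, MBP among them (adjusted p = 0.0067, and adjusted p = 0.26 with an estimated correlation). The handling and heat shock list was not called (adjusted p = 0.202), with a median log2 change of -0.02 against a mean of 0.13. FOS, 1 of its members, stood at 1.62 and then 5.44 FPKM in DBTRG-05MG and at 0.92 and then 1.97 FPKM in U87.

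By size alone at 6 h, the transcription factor gene MAFK, the prostaglandin E synthase PTGES and the complement inhibitor CD55 were over 3-fold higher in both lines. MAFK was at 12.2 and then 48.3 FPKM in DBTRG-05MG and at 9.64 and then 42 FPKM in U87, with limma adjusted p = 0.178. NNMT, the amino acid transporter SLC7A5 and FAM107B followed, with mean log2 changes of 1.75, 1.68 and 1.51. Lower in both lines was the clock output gene DBP (34.2 to 10.3 FPKM in DBTRG-05MG and 6.31 to 2.06 FPKM in U87). The others were TOX2, BCORL1, SLITRK5, the erythropoietin receptor gene EPOR, SH3BP1, LOC400043, UAP1L1 and the microRNA genes MIR4653 and MIR138-1, with mean log2 changes from -1.80 to -1.06. None of these passed the test over all genes. Values at the microRNA genes are poly(A) RNA read at those loci, and mature microRNAs were not measured.

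At 6 h IL11 was the 1 gene called by limma, with 656 genes at an unadjusted p under 0.05 where 618 would be expected by chance. IL11 missed the threshold without any 1 of 5 libraries (DBTRG-05MG 6 and 12 h, U87 0, 6 and 12 h; adjusted p from 0.0548 to 0.137), after median centring (0.0783), with no filter on low values (0.274) and without pairing by line (0.267), which also took the lists called from 11 to 7. The calls of the cAMP and TGF-beta lists held without each library in turn, and the other list calls did not. Leaving out the U87 0 h library ended those of the cytokine (0.64), NF-kappaB (0.992, now lower), JAK and STAT3 (0.106), mesenchymal (0.644) and protease (0.616) lists, and leaving out DBTRG-05MG 6 h ended the last 4 of these (0.318, 0.701, 0.957 and 0.56) and the ribosomal list (0.158). Leaving out DBTRG-05MG 0 h ended those of the ribosomal (0.833), histone (0.323), oligodendrocyte (0.269) and G1/S (0.346) lists. Leaving out U87 6 h ended those of histones (0.473) and oligodendrocyte markers (0.159) and turned the G1/S list to higher (0.000645). A rank-based camera ended the call of the JAK and STAT3 list (0.143) and median centring that of the protease list (0.0605). Removing the pairing by line ended those of the JAK and STAT3 (0.0699), mesenchymal (0.0699), histone (0.0837), protease (0.132) and oligodendrocyte (0.333) lists.

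The middle times asked how the early response went on. IL11 stayed far above its start, at 262 FPKM in DBTRG-05MG and 337 FPKM in U87 at 12 h and at 119 and 329 FPKM at 24 h. Its mean log2 change was 5.18 at 12 h (SE 0.43, limma adjusted p = 0.00868) and 4.60 at 24 h (limma adjusted p = 0.0238), and it was the 1 gene called at each time. IL6 reached 198 FPKM in U87 at 24 h and stood at 15.2 FPKM in DBTRG-05MG. PDE4B held at 16.6 FPKM in DBTRG-05MG and 22.1 FPKM in U87 at 24 h. DIO2 had fallen from its 6 h level to 7.26 and 15.1 FPKM, still above its start in both lines. At an unadjusted p under 0.05 there were 551 genes at 12 h and 433 at 24 h. The call at 12 h was lost without the DBTRG-05MG 12 h, the U87 0 h or the U87 12 h library, and the call at 24 h without the 0, 12 or 48 h library of either line. This left 0 genes in each case. Both calls were also lost after median centring and without pairing by line, with 0 genes called, and with no filter on low values, where 3 and 2 genes were called and IL11 was not among them. Without the 24 h library of 1 or the other line the 12 h count was 3, and without that of DBTRG-05MG the 24 h count was 3. The count was 2 at both 6 h and 12 h without the DBTRG-05MG 0 h, DBTRG-05MG 48 h or U87 48 h library, and a pseudocount of 0.1 gave 3, 3 and 2 genes at 6, 12 and 24 h, IL11 among them each time.

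**Figure D1:**
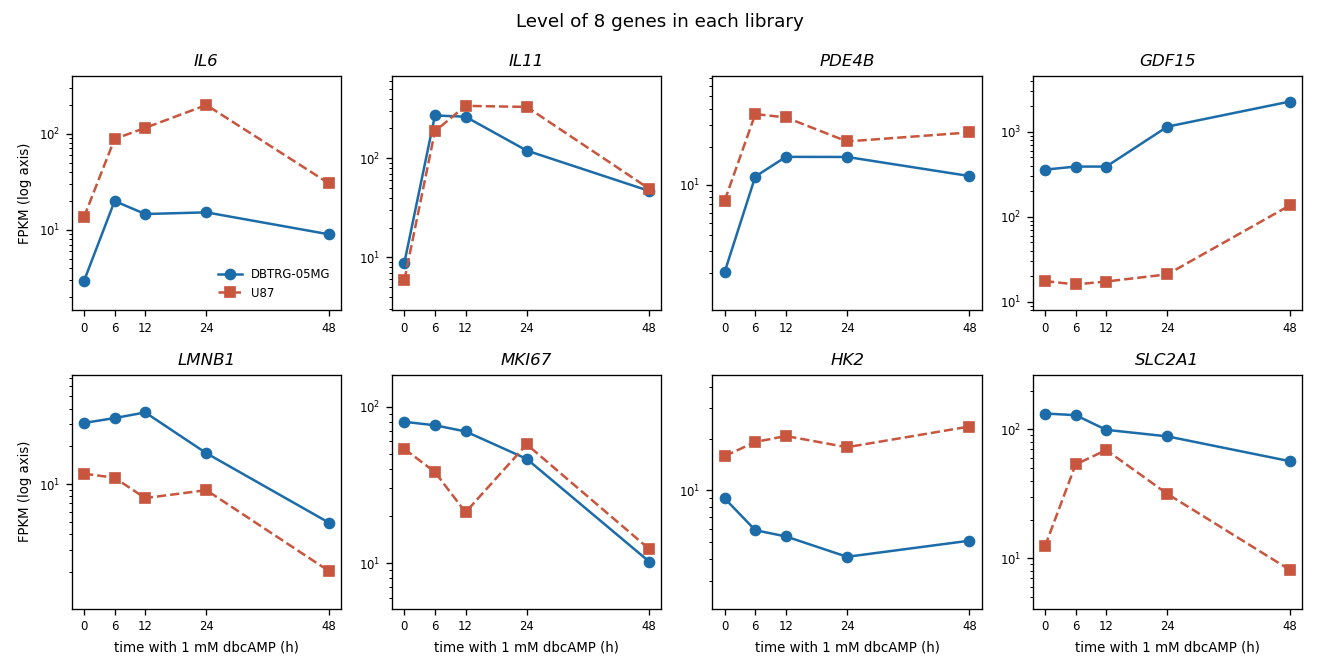
FPKM on a log axis of IL6, IL11, PDE4B, GDF15, LMNB1, MKI67, HK2 and SLC2A1 at 0, 6, 12, 24 and 48 h, with 1 point per library and 1 line per cell line. IL11 rises by 6 h in both lines and is lower again at 48 h, whereas LMNB1 and MKI67 reach their lowest levels at 48 h.

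The last time asked what the cells looked like after 48 h. Genes of cell division were lower together in both lines. Of 49 genes of G1/S and DNA replication, 42 fell adjusted over the list alone and 48 were lower in both lines. As a list, the replication genes had adjusted p = 3.38e-29, and adjusted p = 0.392 with an estimated correlation. MCM5, a subunit of the replicative helicase, fell from 47.2 to 10.95 FPKM in DBTRG-05MG and from 86.3 to 23.4 FPKM in U87. GINS2, CCNA2 and TYMS changed by -1.86, -1.71 and -1.69 on the log2 scale. Of 49 genes of G2 and mitosis, 36 fell adjusted over the list alone and 49 were lower in both lines. The mitosis list had adjusted p = 4.5e-26, and adjusted p = 0.392 with an estimated correlation. The proliferation marker MKI67 fell from 79.9 to 10.2 FPKM and from 53.7 to 12.3 FPKM. The spindle checkpoint kinase gene BUB1B fell from 23.7 to 4.06 FPKM and from 32.2 to 8.11 FPKM, and CDCA8 of the chromosomal passenger complex from 21.3 to 4.29 FPKM and from 30.5 to 7.49 FPKM.

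Markers that fall in senescent cells were lower at 48 h, and markers that rise in them were higher as a list. Of 18 of the former, 11 fell adjusted over the list alone and 18 were lower in both lines. These markers had, as a list, adjusted p = 8.32e-13, and adjusted p = 0.392 with an estimated correlation. Their median relative to all genes was -0.96, beside -1.3 for the replication list and -1.43 for the mitosis list. Their fall was therefore not separated from that of the genes of cell division. The nuclear lamina gene LMNB1, on chromosome 5 (126776623 to 126837020), fell from 30.7 to 4.93 FPKM in DBTRG-05MG and from 12.1 to 2.03 FPKM in U87, a mean log2 change of -2.26 ± 0.31 (SE). UHRF1, SUV39H1 and HELLS, which maintain chromatin marks, changed by -2.03, -1.67 and -1.66. Of 20 markers that rise in senescence, GDF15, a stress-induced cytokine, was the 1 that rose adjusted over the list alone, from 359 to 2276 FPKM and from 17.5 to 136 FPKM. The rising markers together had adjusted p = 0.00445, and adjusted p = 0.421 with an estimated correlation. Of these 20, 9 were higher in both lines, 4 were lower in both and 7 went opposite ways. The cell cycle inhibitor CDKN1A stood at 293 and then 438 FPKM in DBTRG-05MG and at 140.1 and then 399.8 FPKM in U87, with 58.6 FPKM in U87 at 6 h. CDKN2A, another such inhibitor, did not exceed 0.05 FPKM in any library.

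Stress and degradation genes were higher at 48 h. Of 34 genes of the unfolded protein and integrated stress responses, the transcription factor genes ATF3 and CEBPB and the transporter SLC7A5 rose adjusted over the list alone, and 20 were higher in both lines. For both stress responses as 1 list, camera gave adjusted p = 2.59e-07, and adjusted p = 0.392 with an estimated correlation. CEBPB rose from 7.11 to 51.8 FPKM in DBTRG-05MG and from 73.5 to 157 FPKM in U87. Of 32 lysosome and autophagy genes, the cargo receptor SQSTM1 rose adjusted over the list alone, from 169.7 to 539 FPKM and from 126 to 563 FPKM, and 18 were higher in both lines. Lysosome and autophagy genes together had adjusted p = 0.00011, and adjusted p = 0.392 with an estimated correlation. The cAMP and CREB targets were still called, with PDE4B and DUSP1 up adjusted over the list alone. For cAMP targets at 48 h camera gave adjusted p = 7.22e-06, and adjusted p = 0.392 with an estimated correlation. Histones as a list were called higher in the mean of both lines (adjusted p = 0.00445, and adjusted p = 0.499 with an estimated correlation). Their median log2 change was 1.13 in DBTRG-05MG, with 7 of 9 at least 2-fold higher, and -0.01 in U87, with 1 of 9. HIST1H1C and HIST1H2BD rose adjusted over the list alone, by 1.71 and 1.37 on the log2 scale, and 3 of 9 were higher in both lines.

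Secreted factors at 48 h went both ways. IL11 and GDF15 rose and the ErbB ligand NRG1 fell adjusted over the list alone among 35 secretory cytokines and growth factors. Cytokines as a list had adjusted p = 0.00563, and adjusted p = 0.553 with an estimated correlation. MMP10, SERPINE2 and IGFBP7 rose and FAS fell adjusted over the list alone among 31 secreted proteases and matrix genes. Secreted proteases and matrix genes had, as a list, adjusted p = 0.0464, and adjusted p = 0.392 with an estimated correlation. TNFAIP6 was the 1 of 31 NF-kappaB targets that rose adjusted over the list alone, and PTGS2, which makes prostaglandins, stood at 162 FPKM in U87 after 11.4 FPKM at 0 h and below 1 FPKM in DBTRG-05MG at both times. The NF-kappaB list at 48 h had adjusted p = 0.0212, and adjusted p = 0.569 with an estimated correlation. The median log2 changes of the cytokine, protease and NF-kappaB lists were -0.09, -0.08 and -0.07 in DBTRG-05MG and 0.46, 0.23 and 0.79 in U87. Ribosomal proteins such as RPS27 and RPL27 (adjusted p = 0.00011, and adjusted p = 0.569 with an estimated correlation) and respiratory chain genes such as NDUFA1 and COX7A2 (adjusted p = 0.00207, and adjusted p = 0.569 with an estimated correlation) lay higher with 0 members past the threshold adjusted over the list alone. Neuronal markers did so too (adjusted p = 0.00994, and adjusted p = 0.392 with an estimated correlation), with SCG2 at 93.2 and then 444 FPKM in DBTRG-05MG but below 1 FPKM in U87. The neuronal tubulin gene TUBB3 was near its start in both lines, and the astrocyte gene GFAP stayed below 1 FPKM in all 10 libraries.

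By size at 48 h, 3 reductase genes stood beside GDF15, IL11, PDE4B and SQSTM1 at the top of the higher genes. The aldo-keto reductase AKR1C1 was at 26.2 and then 142 FPKM in DBTRG-05MG and at 17.2 and then 216 FPKM in U87. The quinone reductase NQO1 was at 52.2 and then 172 FPKM and at 50.8 and then 285 FPKM, and AKR1B1 at 220.2 and then 688 FPKM and at 1275 and then 5547 FPKM. The calcium-binding S100A4, the kynureninase KYNU and the protease inhibitor TFPI2 were higher by 2.08, 2.05 and 1.76 on the log2 scale. The lowest by the same rule were the AP-1 gene FOSL1 (443.8 to 95.7 FPKM and 571 to 114 FPKM), FAM111B, KIAA1524 and the microRNA genes MIR25 and MIR663A. Their mean log2 changes ran from -2.26 to -1.79, and they stood beside LMNB1, MKI67, CDCA8, BUB1B and MCM5. Here too the values at microRNA genes are not levels of mature microRNAs.

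Further lists were not called at 48 h. IL6 signalling gave adjusted p = 0.149, with IL11 and CEBPB up and FOSL1 down adjusted over the list alone. STAT3 itself was at 48 and then 35.7 FPKM in DBTRG-05MG and at 16.9 and then 25.3 FPKM in U87, and SOCS3 was lower in both. Mesenchymal genes gave 0.232, with S100A4 and the matrix gene SPARC up adjusted over the list alone, and YAP and TEAD targets 0.0898, with ANKRD1 lower in DBTRG-05MG and CTGF lower in both lines. TGF-beta targets gave 0.829, with a median of 0.01 and a mean of -0.07 on the log2 scale, and with TGFBI higher and SMURF2 lower in both lines. Epithelial markers gave 0.0547 (KRT7 up adjusted over the list alone), immune cell markers 0.141 (FCER1G down adjusted over the list alone), endothelial markers 0.714, oligodendrocyte markers 0.334, astrocyte markers 0.423 and neural and glioma stem markers 0.928. Drug transport and temozolomide response genes gave 0.155, and nucleotide, pentose and serine synthesis genes 0.19, with PFAS down adjusted over the list alone. Lipid synthesis and oxidation gave 0.346 (ELOVL6 down adjusted over the list alone), cholesterol synthesis 0.219, interferon response 0.351, mitochondrial biogenesis regulators 0.617, cAMP pathway components 0.951 and heat shock and handling 0.351 (ATF3 up and HSPH1 down adjusted over the list alone). The direction of the test differed in sign from the median or the mean for the cAMP pathway component, lysosome, lipid, nucleotide, interferon, neuronal and handling lists at 6 h and for the astrocyte and TGF-beta lists at 48 h, and the test called none of these there.

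Over all genes, limma called 0 genes at 48 h, where the smallest adjusted p was 0.104 and 1512 genes (458 higher, 1054 lower) had an unadjusted p under 0.05. On simulated data the same fit recovered 16% of genes changed by 1 log2 unit and 92% of those changed by 2. Each simulated change was equal in both lines, with independent noise, so these shares need not hold here. In the real data GDF15, with a mean log2 change of 2.77, was not called. Without the 24 h library of DBTRG-05MG or of U87 the count was 2, namely GDF15 (0.00541 and 0.00598) and IL11 (0.0335 and 0.0347). The calls of the replication, mitosis, senescence, stress response, lysosome and cAMP lists held without each library in turn. Leaving out U87 0 h turned the cytokine (0.675) and NF-kappaB (0.615) lists to lower and ended the call of the neuronal list (0.136), and leaving out U87 48 h ended those of the cytokine (0.637), NF-kappaB (0.598), ribosomal (0.239) and respiratory chain (0.0916) lists. Leaving out DBTRG-05MG 48 h ended those of the histone (0.223) and neuronal (0.178) lists, and leaving out DBTRG-05MG 0 h that of the ribosomal list (0.103). The protease list lost its call without any 1 of 7 libraries (DBTRG-05MG 6 and 24 h and all 5 of U87; 0.0512 to 0.615). Median centring ended the calls of the NF-kappaB (0.142), cytokine (0.0536) and protease (0.14) lists, and removing the pairing by line those of the neuronal (0.115) and protease (0.115) lists. A rank-based camera ended those of the NF-kappaB (0.065) and protease (0.0885) lists, and leaving out both 24 h libraries that of the protease list (0.0545). Of the lists not called, IL6 signalling and mesenchymal genes were called higher without DBTRG-05MG 0 h (0.0371 and 0.00258) or DBTRG-05MG 48 h (0.0163 and 0.000348), and cholesterol synthesis higher without the latter (0.000368). YAP and TEAD targets were called lower without U87 0 h (0.00527) or U87 48 h (0.000895). Epithelial markers were called higher without 1 or both 24 h libraries (0.0394 to 0.0429), and the drug transport list lower without pairing by line (0.0329).

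**Figure D2:**
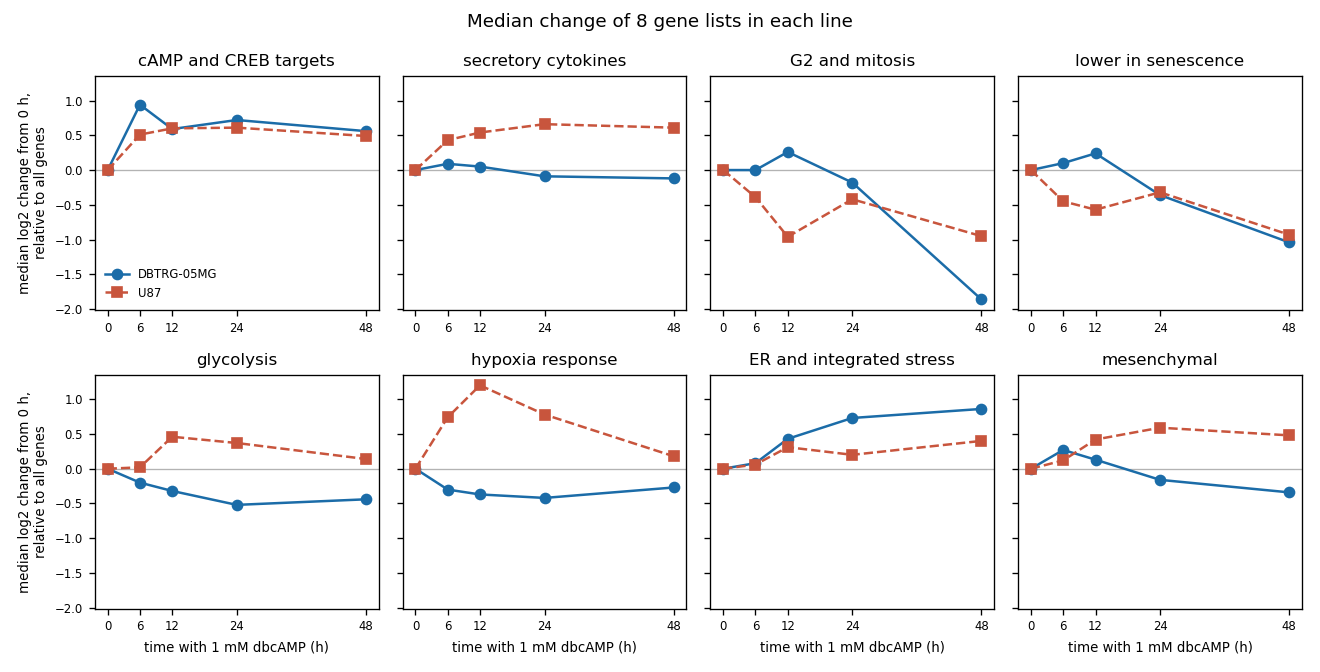
Median log2 change from 0 h of the genes of 8 lists, relative to the median of all tested genes, at 6, 12, 24 and 48 h in each cell line, with 1 point per line and time. The cAMP and CREB targets lie above 0 at each time in both lines, while glycolysis and hypoxia response lie below 0 in DBTRG-05MG and above 0 in U87 at all 4 times.

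Because the series title names IL-6 and a glycolytic phenotype, the genes of sugar metabolism were followed line by line. HK2, the first enzyme of glycolysis, was lower than at 0 h in DBTRG-05MG at each later time (8.99 FPKM at 0 h and 5.11 FPKM at 48 h) and higher in U87 (15.8 and 23.5 FPKM). The glucose transporter SLC2A1 went from 133 to 56.7 FPKM in DBTRG-05MG by 48 h, whereas in U87 it went from 12.4 to 69.2 FPKM at 12 h and was at 8.16 FPKM at 48 h. LDHA, which makes lactate, stood at 1095 and 784 FPKM in DBTRG-05MG at 0 and 48 h, and at 917, 1491 and 734 FPKM in U87 at 0, 12 and 48 h. PFKFB3, a regulator of glycolytic flux, was at 9.38 FPKM in U87 at 0 h, 42.7 FPKM at 6 h and 6.75 FPKM at 48 h, and PKM was lower at 48 h in both lines. The transporter SLC2A3 was the 1 of 26 glycolysis genes that rose at 48 h adjusted over the list alone, from 20.4 to 46.3 FPKM and from 12.2 to 28.6 FPKM.

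As a list, glycolysis was not called in the mean of both lines, with adjusted p = 0.517 at 6 h and 0.814 at 48 h. Its median relative to all genes, which lay at -0.01 in U87 at 48 h without that centring, was -0.20, -0.32, -0.52 and -0.44 at 6, 12, 24 and 48 h in DBTRG-05MG and 0.02, 0.46, 0.37 and 0.14 in U87. Against matched random lists the glycolysis median lay at percentile 0 at each time in DBTRG-05MG. In U87 it lay at percentiles 78.5, 100, 99.6 and 70.3. The hypoxia response list lay at -0.30, -0.37, -0.42 and -0.27 in DBTRG-05MG and at 0.74, 1.20, 0.78 and 0.18 in U87, and was not called in the mean of both lines at 48 h (adjusted p = 0.226). Both lists depended on single libraries: without the U87 0 h library glycolysis was called lower at 6 h (0.000242) and 48 h (0.00762) and hypoxia response lower at 6 h (0.0292). Without the DBTRG-05MG 0 h library glycolysis was called higher at 6 h (0.0234) and 48 h (0.0206), and hypoxia response higher at 6 h (3.52e-08) and 48 h (3.22e-06). Hypoxia response was also called higher at 48 h without the U87 48 h library (0.0393). Other cytokines also differed in level between the lines. IL8 went from 40.2 to 277 FPKM in U87 by 48 h and from 276 to 214 FPKM in DBTRG-05MG. IL1B stood at 887 FPKM in U87 at 24 h after 362 FPKM at 0 h, and LIF was at 81.3 FPKM in U87 and 16.8 FPKM in DBTRG-05MG at 48 h.

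The difference in time course between the lines was tested directly, as a trend over the 5 times. The monoamine transporter gene SLC18A1, on chromosome 8 (20144855 to 20183206), went from 0.53 to 39.1 FPKM in DBTRG-05MG, and the transglutaminase TGM3, on chromosome 20 (2296001 to 2341078), from 0.04 to 6.94 FPKM. Both were listed at 0 in U87 throughout. Their trends differed by -1.20 ± 0.10 and -0.77 ± 0.08 log2 units per step of time (U87 minus DBTRG-05MG, SE, limma adjusted p = 0.00238 and 0.0104). They were the 2 genes called, with 1664 at an unadjusted p under 0.05, and the test restates their rise in DBTRG-05MG, since U87 gave no trend to measure. In DBTRG-05MG alone they rose by 1.20 ± 0.08 and 0.77 ± 0.06 log2 units per step (SE, limma adjusted p = 0.0253 for each). They were among 61 genes whose trend was called in DBTRG-05MG alone, against 0 in U87 alone. For the difference in trend, limma called 0 of the 10682 genes with a mean of at least 1 FPKM in each line. Of these, 1367 had an unadjusted p under 0.05, and the smallest adjusted p was 0.107. The count was 0 with time as log2 hours, 14 with time in hours, 1 with a pseudocount of 0.1, 7 after median centring, 6 with no filter and 5 among protein-coding genes alone. By size at 48 h, COL8A1, the matricellular genes CYR61 and THBS1, the YAP target ANKRD1 and the chemokine CXCL1 were lower than at 0 h in DBTRG-05MG, and all but ANKRD1, which was listed at 0 there at both times, were higher in U87. COL8A1 went from 20.1 to 5.88 FPKM in the former and from 7.95 to 82 FPKM in the latter.

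The trend differed for 14 lists, with 12 more positive in U87. Among these, G1/S and DNA replication had the smallest adjusted p, 4.3e-13 (adjusted p = 0.521 with an estimated correlation). NF-kappaB targets gave adjusted p = 1.65e-08 (adjusted p = 0.263 with an estimated correlation), secretory cytokines 1.65e-08 (adjusted p = 0.166 with an estimated correlation), mesenchymal genes 1.39e-07 (adjusted p = 0.166 with an estimated correlation) and YAP and TEAD targets 1.84e-06 (adjusted p = 0.166 with an estimated correlation). Mitosis genes gave 1.36e-06 (adjusted p = 0.75 with an estimated correlation) and glycolysis 0.000714 (adjusted p = 0.53 with an estimated correlation). The other 5, namely the stem marker, astrocyte, hypoxia, IL6 signalling and TGF-beta lists, gave 0.0468 to 0.0482 (adjusted p from 0.263 to 0.755 with an estimated correlation), and secreted proteases and matrix genes missed the threshold (0.051). The unfolded protein and integrated stress genes had the more positive trend in DBTRG-05MG, with 0.0173 (adjusted p = 0.589 with an estimated correlation), and so did histones, with 0.0173 (adjusted p = 0.437 with an estimated correlation). Without the U87 0 h library 67 genes and 7 lists were called in place of 2 and 14. Without the DBTRG-05MG 0 h, DBTRG-05MG 6 h or U87 48 h library the genes were 12, 5 and 11, and without the DBTRG-05MG 48 h, U87 6 h or U87 24 h library they were 1.

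How far the lines moved was counted as genes at least 2-fold from 0 h. In DBTRG-05MG there were 145 higher and 100 lower at 6 h and 564 and 637 at 48 h. In U87 there were 337 and 300 at 6 h and 264 and 533 at 48 h. Both lines shared 39 higher and 21 lower genes at 6 h, where 4 and 2.4 would be expected if the lines were independent. At 48 h they shared 70 and 198, where 12.1 and 27.5 would be expected. At 24 h they shared 29 and 15, where 8.4 and 8.9 would be expected. Genes higher in DBTRG-05MG and lower in U87 numbered 8, 26, 54 and 24 at 6, 12, 24 and 48 h. Those lower in DBTRG-05MG and higher in U87 numbered 9, 25, 17 and 15. The correlation of log2 changes across genes, which are not independent replicates, was 0.28, 0.09, -0.16 and 0.36 at 6, 12, 24 and 48 h. The median of all genes in U87 lay at -0.15 at 24 and at 48 h. After centring each library on its median the U87 counts at 48 h were 480 higher and 236 lower and at 24 h 477 and 276, in place of 265 and 556. In DBTRG-05MG at 6 h they were 178 and 68.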

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

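Of the tests below, those of trends among genes measured in both lines, of the depth of the U87 24 h library, of scaling, of handling stress and of time in culture were chosen after the results were seen, as was the list test of differing trends.

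By the test of the difference in trend, 2 genes were called, SLC18A1 (-1.20 log2 units per step, U87 minus DBTRG-05MG) and TGM3 (-0.77). Both were listed at 0 in U87 throughout, so this is a rise in DBTRG-05MG of genes not detected in U87, whose 5 libraries at 0 enter the fit with no scatter. Among genes with a mean of at least 1 FPKM in each line 0 were called. The 10 libraries were divided 5 against 5 in 100 ways drawn at random, the real division included. Of these, 2 gave as many genes and 97 gave 0. All divisions but the real one mix the lines, and the fit then has no term for line, so they do not stand for chance alone and this count leaves chance open. The highest other division gave 5452 genes against the real 2. It set DBTRG-05MG at 0 and 6 h with U87 at 12, 24 and 48 h. In that division the standing difference between the lines enters the fit as a difference in trend, so its count does not bear on time courses.

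By the list test on trends, adjusted p was 4.3e-13 for G1/S and DNA replication, 1.36e-06 for G2 and mitosis, 1.65e-08 for NF-kappaB targets, 1.65e-08 for secretory cytokines, 1.39e-07 for mesenchymal genes, 1.84e-06 for YAP and TEAD targets and 0.000714 for glycolysis, all more positive in U87. It was 0.0468 for neural and glioma stem markers (adjusted p = 0.263 with an estimated correlation), and 0.0482 for each of astrocyte markers (adjusted p = 0.263 with an estimated correlation), hypoxia response (adjusted p = 0.755 with an estimated correlation), IL6 signalling (adjusted p = 0.394 with an estimated correlation) and TGF-beta targets (adjusted p = 0.75 with an estimated correlation), again more positive in U87. It was 0.0173 for the stress response genes and 0.0173 for histones, both more positive in DBTRG-05MG. With an estimated correlation 0 of the 14 lists were called.

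Some results lay on opposite sides of 0 in the lines at all 4 later times, a difference that was not tested: 2 list medians, taken relative to all genes, and 5 genes. At 48 h, U87 minus DBTRG-05MG was 0.58 for the relative median of the glycolysis list and 0.45 for that of hypoxia response. It was 4.83 for COL8A1, 3.55 for CXCL1, 1.25 for HK2, 0.97 for STAT3 and -1.55 for the kinase inhibitor gene PKIA (log2). STAT3 at 6 h in DBTRG-05MG, at -0.05, was at 0.05 after median centring. Among all 12352 genes, 614 (5%) moved in opposite directions at all 4 times, and 5 of the 171 named genes did. No group of libraries was large enough to look for outliers.

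Relative to all genes, the glycolysis list lay below 0 in DBTRG-05MG and above 0 in U87. In U87 it stood apart from matched random lists at 12 and 24 h (percentiles 100 and 99.6) but not at 6 and 48 h (78.5 and 70.3). Scaling is argued against for the gap between the lines at 12 h, which was 0.74, and at least 0.78 under both other scalings, but it decides the sign in U87 at 48 h, where the median was -0.01 without centring and 0.14 relative to all genes. Length and GC content are argued against as the whole cause, since 81% of the gap was left after correction (0.78 before, 0.64 after). Time in culture, density or medium stays open, because the series holds 0 untreated libraries at later times, and it cannot be told apart from the compound for this list. The difference between the lines themselves stays open as well, untested with 1 culture series of each.

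The cAMP and CREB targets lay above their start in both lines, with IL6 and IL11. Handling or heat stress stays open: the handling list's median at 6 h lay at percentile 4.2 of matched random lists in DBTRG-05MG and 73.6 in U87, but its members went both ways. At least 2-fold higher were 4 of 17 in DBTRG-05MG and 0 of 17 in U87, where 9 of 33 cAMP targets were, in a single library. Length and GC content are argued against, since 92% of the smaller median was left after correction (0.51 before, 0.47 after). Time in culture or medium stays open, with 0 untreated libraries at later times, and cannot be told apart from the compound.

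The U87 library at 24 h departed from its neighbours in time, with MKI67 at 57.4 FPKM against 21.1 FPKM at 12 h and 12.3 FPKM at 48 h. Its depth was 93.2% of the median of the other 4 U87 libraries, which argues against low depth. Yet it had 5106 genes at 0, against 4446 to 4699 in the other U87 libraries. It had 10873 genes at 1 FPKM or more, against 11199 to 11330. Admixture of DBTRG-05MG RNA is argued against: 29 genes with a median of 151 FPKM in DBTRG-05MG stood at 0.0736 FPKM in this library, within the 0.0731 to 0.188 FPKM of the other U87 libraries. A correction for length and GC content left 103% of the mitosis list's deviation (0.58 before, 0.6 after). A wrong label, RNA quality and a difference in culture were not tested and stay open, as does a return to division, for which no biological explanation was tested.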

How the results depend on the processing

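Protein-coding genes alone, trends among genes with a mean of at least 1 FPKM in each line, the list test of trends, lists after median centring and lists without both 24 h libraries were chosen after seeing the data. Each count of called genes rests on few genes and 2 lines, depth is known only approximately, and the cause of the shifts below was not tested. For the 40 changes of single genes in both lines taken through the alternatives, 701 of 714 values kept their direction and side of the threshold, 8 lost and 5 gained a call, and 0 reversed. Of these changes only that of IL11 at 6 h was called in the main fit, and all 8 losses were its own. For the other changes, keeping a side of the threshold meant staying uncalled, so the total says little about how stable a call was. Values in 1 line have no test. Among them STAT3 at 6 h in DBTRG-05MG went from -0.05 to 0.05 after median centring.

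At adjusted p under 0.10, 2 genes were called at 12 h in place of 1. Median centring gave 0, 0 and 0 genes at 6, 12 and 24 h in place of 1 each, and 7 differing trends (4 higher in U87, 3 in DBTRG-05MG) in place of 2. No filter gave 0, 3 and 2 genes at these times, 0 of them shared with the earlier calls, and 6 trends. A pseudocount of 0.1 gave 3, 3 and 2 genes and 1 trend. Protein-coding genes alone gave 2 at 12 h and 5 trends. Time as log2 hours gave 0 trends and time in hours 14, and a mean of at least 1 FPKM in each line 0. An estimated correlation left 0 of 11 lists at 6 h, 0 of 14 at 48 h and 0 of 14 trends. Without the replicate block, the pairing by line, limma called 0, 0 and 0 genes at 6, 12 and 24 h and 7 lists at 6 h in place of 11; at 48 h it called 0 genes, as before, and ended the calls of the neuronal and protease lists.

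Counts of genes at least 2-fold from 0 h moved with the low-value settings. With a pseudocount of 0.1 they were 528, 848 and 943 in DBTRG-05MG at 6, 12 and 24 h (245, 504 and 591 before) and 1226, 1156, 1486 and 1433 in U87 at 6, 12, 24 and 48 h (637, 651, 821 and 797 before), and 1278 genes differed between the lines in place of 717. With a mean of at least 5 FPKM they were 108, 309 and 366 in DBTRG-05MG and 397 and 416 in U87 at 6 and 12 h.

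Leaving out each library in turn gave 0 to 2 genes at 6 h, 0 to 3 at 12 h, 0 to 3 at 24 h, 0 to 2 at 48 h and 1 to 67 trends (67 without U87 0 h, 12 higher in U87 and 55 in DBTRG-05MG), and 9 to 13 lists at 6 h, 11 to 17 at 48 h and 7 to 15 list trends. The lone library left at a time is assumed to vary like the others. Without U87 0 h the NF-kappaB list reversed at 6 h (0.992, range 9.06e-14 to 0.992) and 48 h (0.615, range 2.18e-09 to 0.615), and the cytokine list at 48 h (0.675, range 1.69e-10 to 0.675). At 6 h, 7 lists not called in the main fit were called under some setting: mitosis lower under 9 (0.00776 to 0.0438), falling senescence markers lower under 5 (0.0154 to 0.0418), the respiratory chain list higher under 3 (0.0154 to 0.0483), YAP and TEAD targets and astrocyte markers higher without DBTRG-05MG 0 h (0.00742 and 0.0263) or U87 6 h (2.78e-05 and 0.00957), and glycolysis and hypoxia response as reported. Without U87 6 h the G1/S list reversed at 6 h (0.000645, range 2.56e-11 to 0.346).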

Other observations

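The genes in this part were chosen after their values were seen, and the NRF2 list was written after 4 of its targets had been seen.

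Some genes of DBTRG-05MG stood far above or below their start at 48 h. The glycoprotein hormone gene STC1 went from 73.1 to 736 FPKM, the acetylcholine receptor subunit CHRNA9 from 3.02 to 75.2 FPKM and the prion-like PRND from 0.62 to 46.6 FPKM. The chemokine gene CCL2 went from 192 to 17.2 FPKM and the imprinted gene MEST from 76 to 9.86 FPKM. In U87 the highest included INSIG1, which restrains sterol synthesis (54.5 to 319 FPKM), the glucose uptake regulator TXNIP (224.7 to 1148 FPKM), the chemokine CXCL2 (19.9 to 118 FPKM) and the mitochondrial superoxide dismutase SOD2 (137.5 to 619 FPKM). These are single libraries with no test.

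AKR1C1, NQO1, SQSTM1 and AKR1B1, all known targets of the antioxidant transcription factor NRF2, were among the genes highest over their start at 48 h in both lines. The hypothesis was that the wider NRF2 program was higher too. It was tested on 32 other targets, of which 29 were measured and 8 sat in another list; a few, such as SLC7A11 and TKT, had been seen among the named genes. Their median relative to all genes at 48 h was 0.99 in DBTRG-05MG and 0.90 in U87, at percentile 100 of matched random lists in both lines, after 0.46 and -0.05 at 24 h. Camera gave p = 3.27e-16 at 48 h, and p = 0.0364 with an estimated correlation, and 11 rose and 0 fell adjusted over the list alone. Ferritin genes were among the most abundant: FTH1 was at 1504 and then 4440.4 FPKM in DBTRG-05MG and at 3199.5 and then 6567 FPKM in U87, and FTL at 588 and then 1470.2 FPKM and at 2245 and then 7892 FPKM. The heme oxygenase HMOX1 was at 25.1 and then 99.8 FPKM and at 111 and then 271 FPKM. A wider increase of NRF2 targets by 48 h remains a hypothesis, found and tested on the same libraries. Without untreated libraries at 48 h, time in culture stays open beside the compound.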
